A study of Homo sapiens with 6 samples.

How the data were processed

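RNA was measured in 6 libraries of THP1 cells, a human monocytic leukaemia line, after 48 h with phorbol 12-myristate 13-acetate (PMA), which drives the line towards a macrophage-like state. The labels put 3 libraries in a control group that carries a scrambled lentiviral hairpin and 3 in a group that carries a lentiviral hairpin against NPL. Transduced cells were selected with puromycin, and libraries were made from poly(A)-selected RNA with a NEBNext Ultra II kit, per the labels' protocols. The hairpin sequences were not given in the sources used here. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

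The authors deposited 1 table of raw read counts per gene for each library, in whole numbers and without normalization. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2, with the genome build GRCh38. The annotation release, the strand setting of the counting and the treatment of multi-mapping reads were not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies, may therefore be split between genes in ways the counts do not show. Each file held 57500 Ensembl genes with the positions of their exons. GENCODE release 29 gave a symbol and biotype for 56898 of them, and 602 stayed without a name. No row lacked a gene identifier.

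Total counts per library were 35945188, 40409594 and 44063378 in the control group and 43597275, 44830653 and 33885312 in the NPL shRNA group. All genes outside the filter on low counts together took under 0.1% of each library. The counts came from PCR-amplified reads without molecular identifiers.

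The comparison was fitted with edgeR 4.0.16 (R 4.3.3): filterByExpr on the group, TMM scaling, robust quasi-likelihood dispersions and the two-sided quasi-likelihood F-test with group as the only term. Genes past a Benjamini-Hochberg adjusted p of 0.05 over all genes tested were called changed. Log2 fold changes are NPL shRNA minus control shRNA. Each standard error (SE) is the absolute log2 fold change divided by the square root of its F statistic. CPM, counts scaled to a common library total, use the TMM factors and are given as mean ± SD over the 3 libraries of a group. All adjusted p-values of single genes come from this fit unless another is named.

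Before the data were examined, 35 gene lists were fixed for pathways, receptors and cell types that fit a sialic acid enzyme in a macrophage-like line, among them 3 lists of markers of other cell types. Each list was tested with camera in limma 3.58.1 on voom values, with the preset inter-gene correlation of 0.01, for lists with at least 5 genes tested. NPL itself was left out of its list's test and median. The alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way. Median log2 fold changes per chromosome were tested the same way, since separately selected pools of cells can differ in copy number.

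The genes named in the text follow a rule fixed in advance. Part a took the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among changed genes with a mean of at least 5 CPM and no overlap between the groups. Part b took the 5 largest in each direction with a mean of at least 100 CPM. Part c took up to 4 changed members of each list by size of change, or up to 2 by smallest p where none changed. Of the 148 genes that the rule selected, 51 share exon bases with another annotated gene, 40 of them with one on the opposite strand. The values of 1 gene that part c selected are not reported here.

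Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE, upper quartile and library size scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, protein-coding genes only, non-robust dispersion, edgeR's glmTreat against 1.5-fold and 2-fold, the replicate number as a block, and leaving out each library in turn. One alternative was added after a trend on gene length was seen: a smooth trend on exon length and GC content per library, fitted with mgcv 1.9.3 and taken out as offsets. In replicate libraries of a group, counts differed by more than sampling noise, with chi-square per degree of freedom of 3.41 to 6.55 over 13522 genes, so no library was counted as a copy of another.

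The fit was tested on 5 simulated data sets per dispersion setting, with counts drawn from the real means, library sizes and dispersions of about 17141 genes, 200 of them changed. With dispersions on the fitted trend, it recovered 59.2% of genes changed 1.25-fold, 71.6% at 1.5-fold, 86.0% at 2-fold and 96.0% at 4-fold, and 4.40% of its calls were false. With dispersions drawn per gene, 10.2% of calls were false, above the 5% that the threshold allows. Camera called a list of 30 genes raised by 0.3 on the log2 scale in 5 of 5 data sets under each dispersion setting. Of 170 unchanged lists it called 5 with dispersions on the trend and 0 with dispersions per gene. Counts of each gene were drawn independently, so these simulations do not test camera on lists whose genes are correlated. Fewer genes changed in these simulations than were called in the data, so recovery and false calls may differ there.

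For the test of hairpin seeds, 3' UTRs came from GENCODE 29 and each 7-mer carried by at least 50 of the 10170 genes with at least 5 CPM was scored by the mean log2 fold change of its carriers minus that of the others, divided by the standard error of this difference. Fold changes were first limited to between -1 and 1 and regressed on the length and GC content of the 3' UTR and the transcript.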

Results

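The data are RNA-seq counts from 6 libraries of THP1 cells after 48 h with PMA. Of these, 3 carried a control shRNA and 3 an shRNA against NPL, which encodes N-acetylneuraminate pyruvate lyase, the enzyme that splits sialic acid into N-acetylmannosamine and pyruvate. Libraries held 33885312 to 44830653 counts over annotated genes. The comparison asks which transcripts differ when NPL is knocked down in macrophage-like cells.

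NPL (ENSG00000135838, chromosome 1, 182789293 to 182830384, GRCh38) had raw counts of 1970, 2281 and 2376 in the control libraries and 203, 212 and 133 in the NPL shRNA libraries. This was 55.6 ± 1.41 CPM against 4.40 ± 0.435 CPM (SD, n = 3 each), a 12.5-fold decrease (log2 fold change -3.65, SE 0.07, adjusted p = 1.79e-25). Every library matched its label. Of the adjacent protein-coding genes tested, RGS8, DHX9 and LAMC1 did not pass the test, and RGS16 was higher by 0.14 on the log2 scale (adjusted p = 0.00101).

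In cells with NPL shRNA, 15 of 22 inflammatory genes under NF-kB were lower and 0 higher (camera adjusted p = 5.32e-15; adjusted p = 0.0899 with an estimated correlation). Of 34 interferon-stimulated genes, 25 were higher and 0 lower (camera adjusted p = 3.12e-23; adjusted p = 0.26 with an estimated correlation). The transcript of CXCL8, a neutrophil-attracting chemokine, was at 366.8 ± 3.26 CPM in control and 196.7 ± 9.35 CPM in NPL shRNA libraries. MMP9, a secreted gelatinase, went from 1023 ± 11.6 to 594.9 ± 14.9 CPM. SCG2, which encodes the secretory granule protein secretogranin II, rose from 9.20 ± 0.405 to 37.3 ± 0.680 CPM, and COL4A1 from 25.6 ± 1.08 to 58.5 ± 0.472 CPM (SD, n = 3 for each mean).

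**Figure D1:**
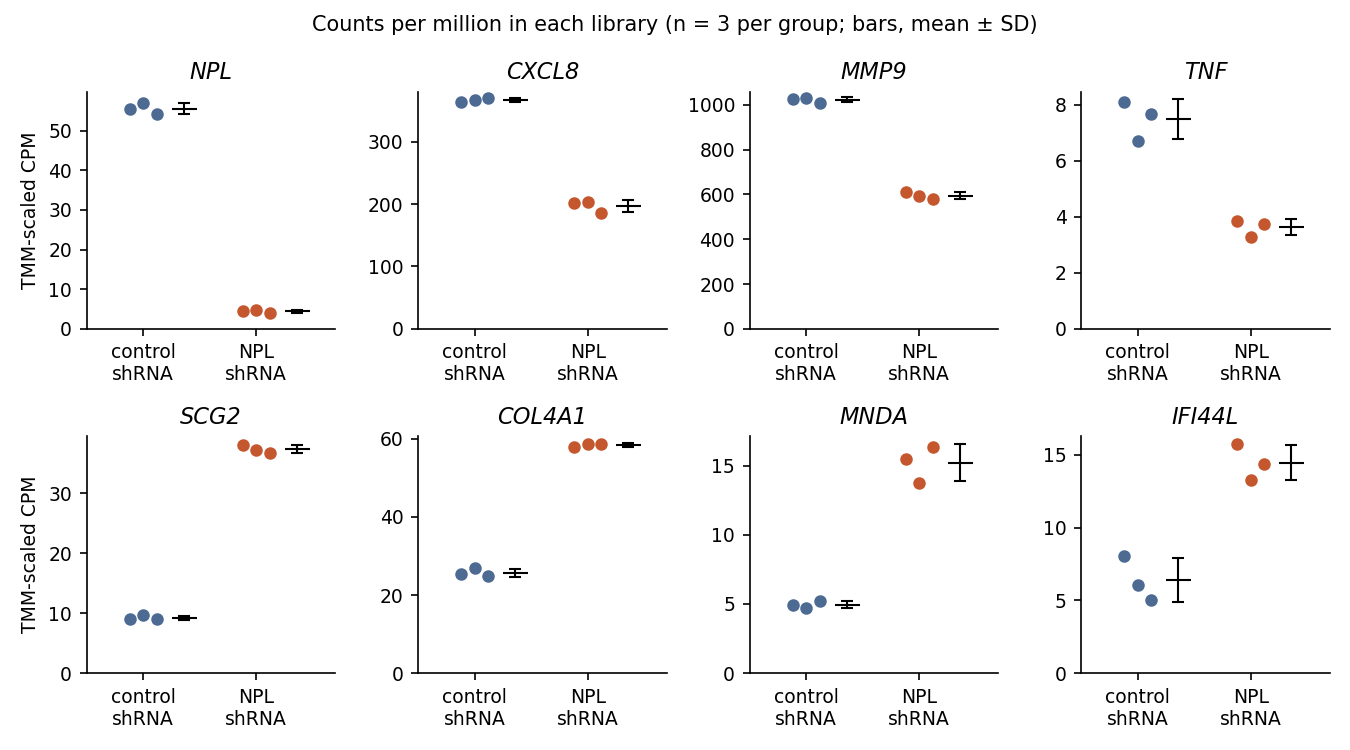
TMM-scaled CPM of 8 genes in each library (points), with the mean ± SD of 3 libraries beside them, on axes that start at 0. For each gene the 3 control shRNA libraries and the 3 NPL shRNA libraries do not overlap, which the rule that selected these genes required. Of all genes tested, 33.0% do not overlap. NPL lies at 55.6 CPM on average in control and 4.40 CPM in NPL shRNA libraries.

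Of 17395 genes tested, 3131 changed, 1545 higher and 1586 lower in NPL shRNA cells, and 2936 of them were protein-coding. Most changes were small: 2633 of the changed genes differed by under 1.5-fold, and 177 differed at least 2-fold, 144 higher and 33 lower. With scaling by library size alone the split was 1908 higher and 1160 lower, so the balance between directions depends on the scaling. The 2-fold count fell to 93 in DESeq2, to 81 with a filter of 1 CPM in 3 libraries, and to 10 when edgeR's glmTreat tested against 2-fold itself.

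**Figure D2:**
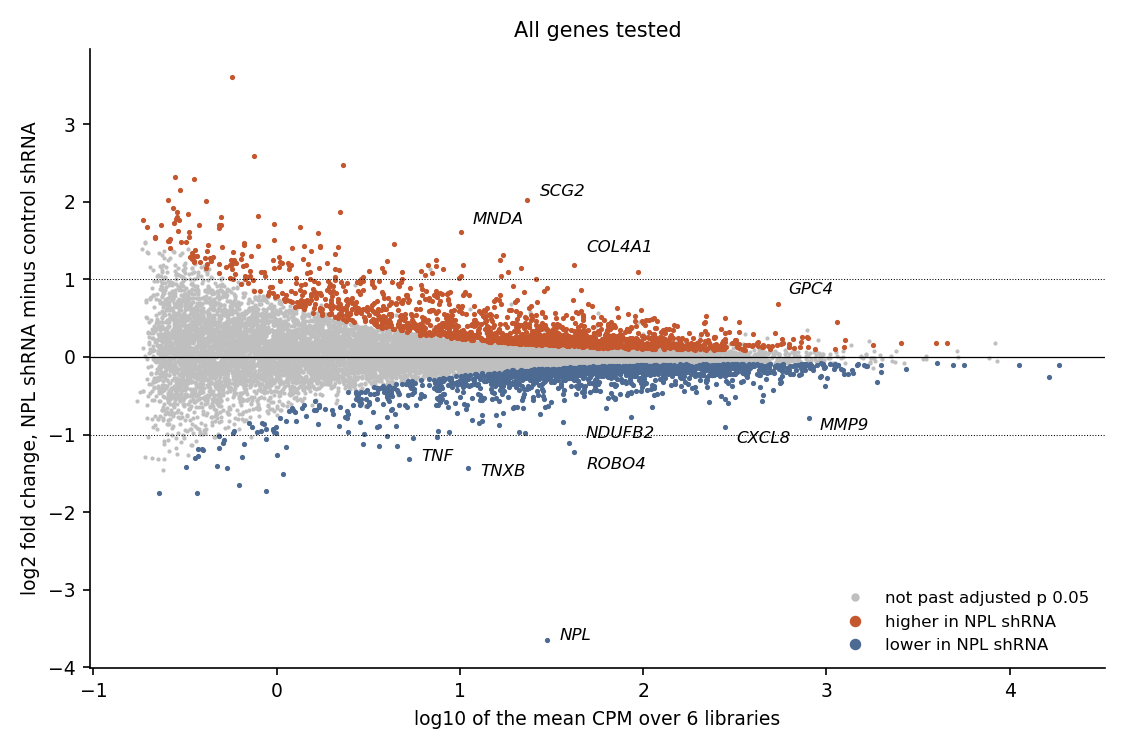
Log2 fold change (NPL shRNA minus control shRNA) against the log10 of the mean CPM for the 17395 genes tested. Coloured points are the 1545 genes higher and 1586 genes lower at an adjusted p under 0.05, dotted lines mark 2-fold, and NPL stands apart at -3.65.

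Among genes with a mean of at least 5 CPM, the largest decreases after NPL were in TNXB (-1.43, SE 0.09), which encodes the matrix protein tenascin-X, in the chemokine gene CCL4L2 (-1.31, SE 0.12), in the endothelial guidance receptor gene ROBO4 (-1.23, SE 0.05) and in NDUFB2 (-1.10, SE 0.06), a subunit of respiratory complex I. TNF (-1.05), LIF (-1.04), CCL3L1 (-0.98), S100A9 (-0.97) and CXCL3 (-0.97) followed. TNXB, CCL4L2 and CCL3L1 have near-identical copies in the genome, and 27.9% of the exon bases of NDUFB2 overlap BRAF on the other strand, so their counts are less certain. The largest increases were in SCG2 (2.02, SE 0.06), MNDA (1.61, SE 0.09), an interferon-inducible nuclear protein of myeloid cells, MDK (1.32, SE 0.07), which encodes the growth factor midkine, ATP6V0D2 (1.26, SE 0.07), a subunit of the vacuolar proton pump, and the Notch ligand gene DLL1 (1.25, SE 0.11). IFI44L (1.19), COL4A1 (1.19), NOG (1.18), VAT1L (1.15) and PRG2 (1.14) completed the 10. Adjusted p-values of these genes, NPL aside, ranged from 8.2e-20 for SCG2 to 8.44e-06 for IFI44L. PRG2 shares 43.0% of its exon bases with AP000781.2 on the same strand, so its count is less certain too.

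Among abundant genes, with a mean of at least 100 CPM, CXCL8 (-0.90, SE 0.03), MMP9 (-0.78, SE 0.03), FCGBP (-0.65, SE 0.05), the complement gene C3 (-0.59, SE 0.03) and the amino acid transporter gene SLC38A1 (-0.58, SE 0.04) fell most. The largest increases were in the cell surface proteoglycan gene GPC4 (0.68, SE 0.03), LY6E (0.53, SE 0.07), ATP9A (0.50, SE 0.04), NREP (0.50, SE 0.03) and the integrin gene ITGA1 (0.49, SE 0.04).

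Of the 34 gene lists with enough genes for camera, 12 moved relative to all other genes, 9 of them lower and 3 higher. With an estimated inter-gene correlation, camera called 0 of the 34 at an adjusted p of 0.05, while 6 had an unadjusted p under 0.05 and fry called 19. Fry but not camera called the lists of sialyltransferases, LXR targets and hypoxia higher. It called those of sialic acid metabolism, cholesterol synthesis, complement, macrophage markers and alternative activation lower. LXR targets had a median of -0.01 and complement genes one of 0.05, each against the direction of fry.

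**Figure D3:**
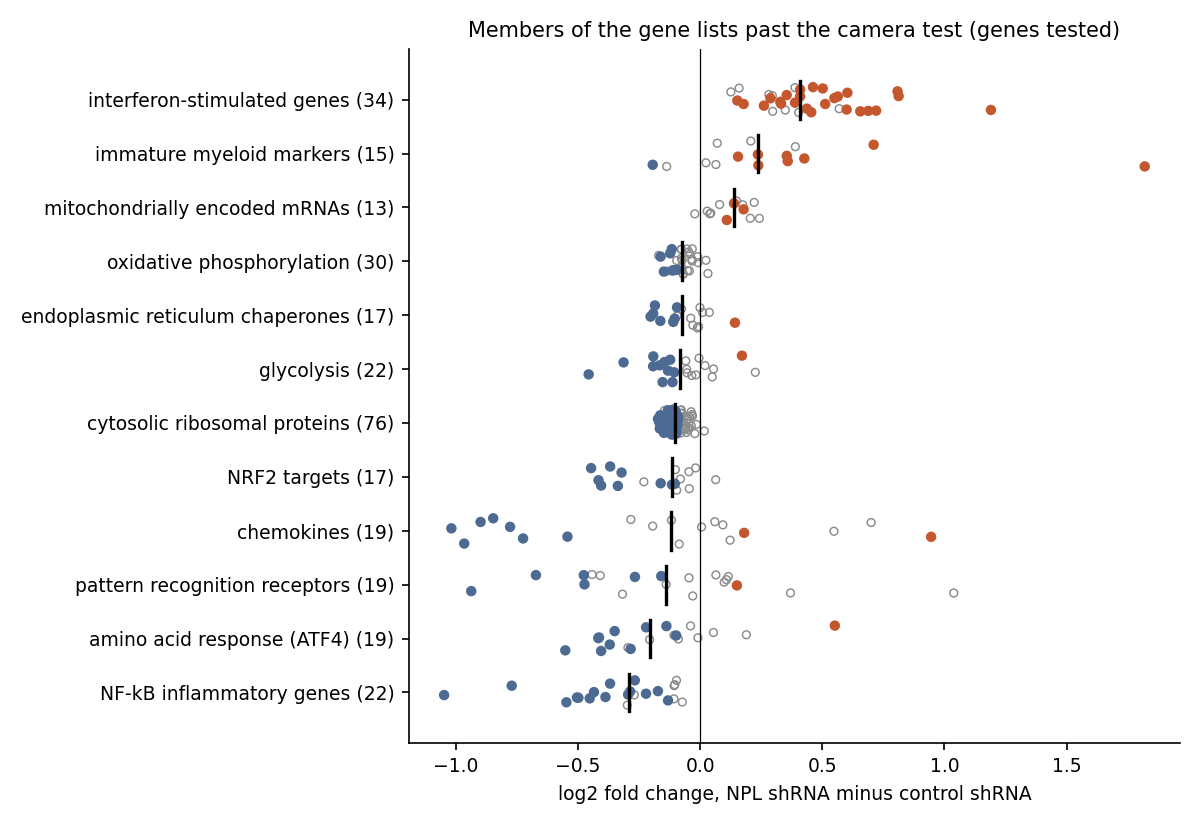
Log2 fold change (NPL shRNA minus control shRNA) of each member of the 12 lists that passed camera. Filled points passed the test for single genes, open points did not, vertical bars are list medians, and the number of genes tested is in brackets; the interferon-stimulated list has the highest median, 0.41, and the NF-kB list the lowest, -0.29.

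Inflammatory genes under NF-kB, the transcription factor that drives cytokine expression, fell in 15 of 22 members tested and rose in 0 (17 lower when adjusted over the list alone). TNF, TNFAIP6 (-0.77), SOD2 (-0.55, from 334.3 ± 14.2 to 228.8 ± 11.6 CPM) and EBI3 (-0.50) fell most, and the list median was -0.29 (camera adjusted p = 5.32e-15; adjusted p = 0.0899 with an estimated correlation). Of 19 chemokine genes, 7 fell and 2 rose, with the same counts adjusted over the list alone. CXCL2 (-1.02), CXCL3 and CXCL8 fell, while CCL1 (0.95, at 1.87 ± 0.204 CPM with NPL shRNA) rose. The chemokine median was -0.12 (camera adjusted p = 0.000204; adjusted p = 0.252 with an estimated correlation), and it was 0.02 without replicate 2 of the NPL shRNA group. Pattern recognition receptors, which sense microbial products, fell in 6 of 19 members and rose in 1 (8 and 3 adjusted over the list alone). CLEC5A (-0.94), TLR7 (-0.67), the lipopolysaccharide co-receptor gene CD14 (-0.48) and LY96 (-0.47) fell. This list was near the threshold (camera adjusted p = 0.0386; adjusted p = 0.26 with an estimated correlation), and its call was lost on protein-coding genes only (0.0696) and without control replicate 2 (0.0537) or NPL shRNA replicate 1 (0.0502), in a range of 0.00524 to 0.0696 over 14 alternatives. Without NPL shRNA replicate 1, 11 of its members passed the test in place of 7. Among 16 inflammasome and pyroptosis genes, AIM2 (0.71) was among 2 that rose, and GSDME (-0.41), NINJ1 (-0.37) and NLRP12 (-0.37) fell (3 and 3 adjusted over the list alone).

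Interferon-stimulated genes moved the other way. Of 34 tested, 25 rose and 0 fell (31 and 0 adjusted over the list alone), all 34 had a log2 fold change above 0, and the list median was 0.41 (camera adjusted p = 3.12e-23; adjusted p = 0.26 with an estimated correlation). IFI44L rose from 6.40 ± 1.53 to 14.5 ± 1.23 CPM, and IFIT2 (0.81), IFITM1 (0.81) and IFIT1 (0.72), all antiviral effectors, also rose. IFITM1 shares 32.5% of its exon bases with IFITM2. Within each group, IFI44L, IFIT1, IFIT2 and IFITM1 ranked the libraries alike. IFI44L was at 8.06, 6.08 and 5.05 CPM in the control libraries, and IFIT2 at 12.45, 7.88 and 9.97 CPM in the NPL shRNA libraries. The members are therefore not independent observations, and the number that changed ran from 19 to 34 over the alternatives. The interferon genes themselves were near absent: 21 genes held 4 counts in total over the control libraries and 0 over the NPL shRNA libraries, and none was tested.

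Targets of NRF2, the regulator of antioxidant genes, fell in 9 of 17 members and rose in 0 (12 lower adjusted over the list alone), led by HMOX1 (-0.45), which encodes haem oxygenase 1, NQO1 (-0.42), the cystine transporter gene SLC7A11 (-0.40) and ABCC3 (-0.37). Their median was -0.11 (camera adjusted p = 6.08e-09; adjusted p = 0.0899 with an estimated correlation). Genes of the amino acid response under ATF4 fell in 10 of 19 members (11 adjusted over the list alone), among them TRIB3 (-0.55), PHGDH (-0.42), the entry enzyme of serine synthesis, and CHAC1 (-0.41), while 1 member, ATF3, rose (0.55), or 2 adjusted over the list alone. The ATF4 list had a median of -0.21 (camera adjusted p = 0.000148; adjusted p = 0.0899 with an estimated correlation). Endoplasmic reticulum chaperones and their partners fell in 7 of 17 members and rose in 1 (8 and 1 adjusted over the list alone), with CRELD2 (-0.20), HERPUD1 (-0.19), MANF (-0.18) and SDF2L1 (-0.16) ahead. Their median was -0.08 (camera adjusted p = 0.0162; adjusted p = 0.252 with an estimated correlation), the list was not called with scaling by library size alone (0.0679, in a range of 0.000188 to 0.0679), and in place of 8 members 3 passed without control replicate 1 and 5 with upper quartile or library size scaling or without control replicate 2 or NPL shRNA replicate 2.

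Shifts in housekeeping and energy genes were smaller. Cytosolic ribosomal protein genes fell in 47 of 76 members and rose in 0 (60 lower adjusted over the list alone), with a median of -0.10 (camera adjusted p = 1.76e-19; adjusted p = 0.276 with an estimated correlation). RPL13 (-0.17), RPS16 (-0.17), RPS15 (-0.16) and RPS14 (-0.16) fell most, and many genes of this family have near-identical pseudogenes. Fewer of them passed with scaling by library size alone (24) or by upper quartile (30), without NPL shRNA replicate 2 (25) and without control replicate 3 (31). Glycolytic genes fell in 11 of 22 members and rose in 1 (the same counts adjusted over the list alone), and PFKM (-0.46), HK3 (-0.31), PKM (-0.19, from 2119 ± 17.5 to 1855 ± 89.6 CPM) and HK1 (-0.19) led a median of -0.08 (camera adjusted p = 0.000241; adjusted p = 0.276 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 7 of 30 members and rose in 0, adjusted either way, with COX5A (-0.16), UQCRFS1 (-0.15), SDHC (-0.12) and COX7C (-0.12) ahead and a median of -0.07 (camera adjusted p = 0.000148; adjusted p = 0.308 with an estimated correlation). This count was 3 with scaling by library size alone and 4 with upper quartile scaling or without any 1 of control replicates 1 and 3 and NPL shRNA replicates 2 and 3. Of 13 mitochondrially encoded mRNAs, MT-ND5 (0.18), MT-ND3 (0.14) and MT-ND4L (0.11) rose and 10 did not pass the test, adjusted either way. The list median was 0.14 (camera adjusted p = 0.000241; adjusted p = 0.484 with an estimated correlation), fry did not call the list (adjusted p = 0.294), and the mitochondrial share of counts overlapped between the groups, at 2.64% to 3.03% in control and 2.95% to 3.32% in NPL shRNA libraries. The count of 3 was 8 with limma-voom or non-robust dispersion, 5 with no filter on low counts, 1 without control replicate 2, NPL shRNA replicate 1 or NPL shRNA replicate 2, and 0 with length and GC offsets.

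Markers of myeloid maturity shifted in part. Immature myeloid markers rose in 8 of 15 members and fell in 1, adjusted either way, with a median of 0.24 (camera adjusted p = 2.28e-05; adjusted p = 0.0899 with an estimated correlation). MS4A3 (1.82, from 0.340 ± 0.184 to 1.24 ± 0.428 CPM), the progenitor transcription factor gene MYB (0.71), the growth factor receptor gene KIT (0.43) and ELANE (0.36), which encodes neutrophil elastase, rose. Macrophage markers went both ways, 7 higher and 9 lower of 25 (8 and 11 adjusted over the list alone): AXL (0.80) and CHIT1 (0.46) rose, and FOLR2 (-0.61) and CD14 fell. Genes of alternative activation rose in 2 of 13 members, FCER2 (0.72) and CD209 (0.26), and fell in 4, among them CTSC (-0.22) and KLF4 (-0.18), or 2 and 6 adjusted over the list alone. Neither the macrophage nor the alternative activation list passed camera.

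In the pathway of NPL itself, 6 of 21 genes of sialic acid and amino sugar metabolism were lower, NPL included, and 1 was higher, with the same counts adjusted over the list alone. AMDHD2 (-0.45), RENBP (-0.23), which encodes the N-acetylglucosamine 2-epimerase, the lysosomal sialidase gene NEU1 (-0.19) and GNPDA1 (-0.18) fell. Of 15 sialyltransferases, which attach sialic acid to glycans, ST8SIA5 (0.36), ST3GAL3 (0.25) and ST3GAL5 (0.24) were among 4 that rose and ST3GAL2 (-0.15) fell (5 and 1 adjusted over the list alone). Among 12 Siglecs, receptors that bind sialic acid, SIGLEC1 rose (0.55, from 30.8 ± 1.97 to 44.9 ± 4.83 CPM), and SIGLEC5 (-0.85), SIGLEC15 (-0.54) and CD22 (-0.09) fell, adjusted either way. SIGLEC5 was at about 1 CPM and shares 74.5% of its exon bases with AC018755.2 on the same strand and 2.9% with SIGLEC14, so its count is less certain. The Siglec count of 4 was 2 with the filter of 1 CPM in 3 libraries and without any 1 library other than control replicate 1, and the sialyltransferase count of 5 was 3 in DESeq2 and without control replicate 1 or 2 or NPL shRNA replicate 1 or 2. None of the 3 lists passed camera, where the adjusted p of the sialyltransferases was 0.0538. Fry called the sialic acid list lower (adjusted p = 0.0105, NPL left out) and the sialyltransferases higher (adjusted p = 0.00427), and did not call the Siglecs (adjusted p = 0.252).

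Lipid genes moved individually. Of 22 genes of cholesterol synthesis and its control, 3 rose and 5 fell (3 and 8 adjusted over the list alone): CYP51A1 (-0.53), LSS (-0.35) and SQLE (-0.34), enzymes of the sterol pathway, fell, and the sterol carrier gene STARD4 (0.39) rose. Targets of LXR, the oxysterol receptor, rose in 2 and fell in 3 of 12 members (4 and 3 adjusted over the list alone), with the cholesterol exporters ABCG1 (-0.59) and ABCA1 (-0.31) and the receptor gene NR1H3 (-0.25) lower and APOC1 (0.48) higher. CYP51A1 shares 78.8% of its exon bases with LRRD1 and APOC1 43.2% with AC011481.3, both on the same strand, so their counts are less certain. Among 18 genes of lipid uptake and storage, 4 rose and 2 fell, adjusted either way: the lipid droplet gene PLIN2 (-0.38) and SCARB1 (-0.23) fell, and the scavenger receptor genes OLR1 (0.29) and CD36 (0.19) rose. Lysosomal genes rose in 6 and fell in 9 of 28 members (7 and 10 adjusted over the list alone), with ATP6V0D2, CTSK (0.45) and SCARB2 (0.30) higher and CTSH (-0.23) lower. None of these 4 lists passed camera. Fry called the LXR targets higher (adjusted p = 0.00159), against their median of -0.01, and the cholesterol list lower (adjusted p = 0.019).

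Among 17 genes of MHC class I presentation, HLA-F rose (0.73) and 3 fell, adjusted either way, among them HLA-C (-0.15) and HLA-B (-0.11), whose similar sequences make their counts less certain. HLA-DMB (0.68) was the 1 of 9 class II genes that changed, adjusted either way, and it did not pass without control replicate 3 or NPL shRNA replicate 3. Complement genes fell in 4 of 19 members, among them CFP (-0.65), C3 and the receptor gene C5AR1 (-0.26), and rose in 3, among them C3AR1 (0.25), or 5 and 6 adjusted over the list alone. None of these 3 lists passed camera.

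Matrix and fibrinolysis genes were split, 9 higher and 13 lower of 30 (10 and 14 adjusted over the list alone). COL4A1, COL4A2 (1.10, from 59.9 ± 2.86 to 128.1 ± 5.80 CPM), COL6A3 (1.01) and SERPINB2 (0.85) rose, while MMP9 fell. Adhesion and migration genes rose in 8 and fell in 5 of 28 (11 and 5 adjusted over the list alone): ITGB3 (0.86) and the chemokine receptor gene CCR2 (0.82) rose, and SELPLG (-0.67) and CXCR4 (-0.30) fell. Neither list passed camera. ITGB3 shares 51.6% of its exon bases with AC068234.1 on the same strand, so its count is less certain.

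Proliferation genes rose in 4 of 27 members, among them CDK1 (0.24) and MKI67 (0.22), and fell in 4, among them the replication helicase genes MCM5 (-0.22) and MCM2 (-0.21), adjusted either way; the count of 8 was 4 without NPL shRNA replicate 2 and 5 without NPL shRNA replicate 3. Of 18 targets of p53, 3 rose and 2 fell, adjusted either way, with GDF15 (0.17), MDM2 (0.16) and BTG2 (0.14) higher and AEN (-0.15) lower, a count of 5 that was 2 without NPL shRNA replicate 2, and 3 with scaling by library size alone or without control replicate 1 or NPL shRNA replicate 3. Hypoxia genes rose in 2 of 17 members, VEGFA (0.45) and NDRG1 (0.41), and fell in 3, among them TMEM45A (-0.54) and BNIP3 (-0.23), or 3 and 3 adjusted over the list alone; this count of 5 was 3 in DESeq2 and without control replicate 1 or NPL shRNA replicate 1 or 2. Early response genes rose in 5 and fell in 6 of 23 (6 and 6 adjusted over the list alone), with ATF3, EGR2 (0.41) and EGR1 (0.39) higher and BATF (-0.40) lower. HIST2H2BE (-0.17) was the 1 of 11 replication-dependent histone genes that changed, adjusted either way, and 0 passed in DESeq2, with scaling by library size alone, or without control replicate 1 or 2 or NPL shRNA replicate 2 or 3, while 2 passed without control replicate 3. None of these 5 lists passed camera.

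Of the lists of markers of other cell types, the lymphoid and the stromal, epithelial and endothelial lists did not pass camera, and the erythroid and platelet list had too few genes for it. Of 9 lymphoid markers, PAX5 rose (1.15, from 2.32 ± 0.306 to 5.18 ± 0.412 CPM) and TRAC fell (-0.20, from 119.1 ± 1.92 CPM), or 2 and 2 adjusted over the list alone. None of 4 erythroid and platelet or 12 stromal, epithelial and endothelial markers passed edgeR's test, adjusted either way, and 0 of both did in DESeq2; without control replicate 3 or NPL shRNA replicate 1, 1 of the 12 did. The smallest p-values there were for GP1BA (0.85, adjusted p = 0.122), PPBP (-0.91, adjusted p = 0.137), KRT18 (0.64, adjusted p = 0.0894) and KRT8 (0.41, adjusted p = 0.183). The median, mean and camera direction of a list did not share a sign for LXR targets, lipid uptake, lysosome, MHC class I, complement, p53 targets, matrix remodelling and lymphoid markers.

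Genes of a chromosome did not move together past the test: limma's camera called 0 of 23 chromosomes, and 1 had an unadjusted p under 0.05 (chromosome 13, adjusted p = 0.0728). Median log2 fold changes per chromosome lay between -0.02 and 0.05.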

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

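The length and GC offsets were chosen after a trend on length was seen. The decrease of NPL held under all 17 alternatives that refit each gene, with log2 fold changes between -3.69 and -3.58. The number of changed genes (3131) lay between 2520 and 3318 with all 6 libraries, and between 2222 and 2970 when each library was left out in turn. Each of these fits kept 68.4% to 99.4% of the calls, and 0 shared calls changed direction. The share of calls that were higher ran from 44.6% with length and GC offsets to 62.2% with library size alone, and no scaling moved the median of all genes by more than 0.03 on the log2 scale. The count at 2-fold was less stable. It was 93 in DESeq2 (75 higher, 18 lower), whose own filter tests fewer genes, and 81 with the filter of 1 CPM in 3 libraries (66 higher, 15 lower), which removes low genes by construction. It was 10 with glmTreat against 2-fold, and glmTreat against 1.5-fold called 67 genes; both ask for a larger change by construction. Leaving out each library gave 149 to 193 genes at 2-fold and 11 to 14 lists. The 12 lists called by camera became 0 with an estimated correlation and 19 with fry; camera and fry shared 11 of their lists, and the cause was not tested. The chemokine median (-0.12) ranged from -0.20 without NPL shRNA replicate 1 to 0.0188 without NPL shRNA replicate 2, where it changed sign (camera adjusted p = 0.00142, in a range of 1.18e-06 to 0.00142); the cause was not tested. Among 147 other named genes, 2368 of 2494 values kept direction and side of the threshold, 124 fell short of it, 2 passed it newly and 0 changed sign. The number of changed members of a list moved by over 1.5 times in 59 of 595 values. Equal replicate numbers did not pair the libraries: the correlations of their deviations from the group means were 0.02, -0.02 and -0.03. With the replicate block, 2667 genes changed and 12 lists passed camera; Siglecs went from 4 to 2 changed members, sialyltransferases from 5 to 3 and endoplasmic reticulum chaperones from 8 to 5. No chromosome passed under library size scaling, with genes of at least 10 CPM or with an estimated correlation. At this depth, the simulated recovery of 59.2% for 1.25-fold changes limits what can be said of small shifts.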

Other observations

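The tests of gene families and of the reagent, and those of the 7-mer beyond its score, were chosen after the result was seen, and the length and GC offsets after a trend on length was seen. Of 34 collagen genes tested, 14 were higher with NPL shRNA and 0 were lower, and the others did not pass the test. The median log2 fold change was 0.41 (camera adjusted p = 3.6e-11 over 8 families looked at, and 0.0106 with an estimated correlation). The family was chosen after some members had been seen to rise, and these stay in the test, so its p-values partly restate that. The median lay between 0.41 and 0.44 under 4 scalings, a weak check, since a scaling moves all genes nearly alike. Beside the basement membrane chains COL4A1 and COL4A2, the risers included COL24A1 (1.06), COL12A1 (0.97), COL22A1 (0.74) and COL18A1 (0.68), and the laminin chain genes LAMA3 (1.09) and LAMA4 (1.09) rose among 10 laminins, of which 0 fell. Of 6 glypicans, cell surface heparan sulfate proteoglycans, GPC4 (0.68), GPC1 (0.57) and GPC3 (0.47) rose and GPC5 (-0.37) fell (adjusted p = 0.0584 with an estimated correlation).

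S100 genes, which encode small calcium-binding proteins released by myeloid cells, went the other way. Of 13 tested, 6 were lower and 0 higher, with a median of -0.43 (camera adjusted p = 8.88e-07, and 0.129 with an estimated correlation). The median lay between -0.43 and -0.41 under 4 scalings, again a weak check, since a scaling moves all genes nearly alike. S100A9 (-0.97), S100A3 (-0.62), S100A4 (-0.57), S100A6 (-0.50) and S100A10 (-0.43) fell most. In a set of 9 TNF superfamily ligand genes that leaves out TNF itself, 5 rose, among them TNFSF13B (0.63), TNFSF9 (0.51) and TNFSF10 (0.48). In that set TNFSF11 (-0.71) fell (camera adjusted p = 0.129 with an estimated correlation). TNF, the ligand left out, fell by more (-1.05), so the count does not cover the whole family. Annexins fell in 2 of 10 members, ANXA5 (-0.31) and ANXA4 (-0.16), glutathione genes fell in 5 and rose in 1 of 18, and tetraspanins rose in 6 and fell in 5 of 24. NDUFB2 (-1.10) lies beside ADCK2 (0.18) and BRAF (0.17), which were higher, and it fell further than each of the 7 lower genes of the oxidative phosphorylation list, where COX5A (-0.16) fell most.

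Genes with few annotated exon bases were lower in NPL shRNA libraries than genes with many, a trend that could have lowered compact housekeeping genes. Exon length here counts every annotated exon of a gene, over all its transcripts. Across 10393 genes, which are not independent replicates, log2 fold change correlated with exon length at a Spearman rho of 0.248, and at 0.052 once length and GC trends were taken out per library. Against that trend as the whole cause, the median of ribosomal protein genes was -0.0902 after it was taken out (-0.101 before). That of oxidative phosphorylation genes was -0.0708 (-0.0746 before). Both were more than 2 standard errors from 0. These standard errors come from the spread over the genes of a list, which are not independent replicates. Both lists passed camera at the preset correlation but not with an estimated one (adjusted p = 0.279 and 0.381 with an estimated correlation). For glycolysis the median was -0.076 after the trend was taken out (-0.0822 before), with a standard error of 0.04. This median lay within 2 standard errors of 0, so the test cannot decide for glycolysis. Because the offsets used all exon bases of a gene, they could not take out a trend on the length of the transcripts present. Such a trend was not tested and stays open for these lists. What made ribosomal protein, respiratory and glycolytic genes lower stays open, and loss of NPL is the biological explanation that the design names.

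Of 34 interferon-stimulated genes 25 rose, and of 22 NF-kB genes 15 fell. The trend on exon length and GC does not account for either as the whole cause. After it was taken out, the medians were 0.403 and -0.269, against 0.41 and -0.29 before (camera adjusted p = 0.279 and 0.14 with an estimated correlation). Each arm holds 1 reagent, and the labels do not say how many transductions or selected pools it came from. For the interferon median of 0.409, a response to the hairpin or a trait of the selected cells cannot be told apart from NPL loss. A second hairpin or a rescue would part them. The same limit holds for the other differences between the groups, the NF-kB list included. Interferon genes gave no value to decide, since 21 of them held 4 counts in control and 0 in NPL shRNA libraries. None of the 22 NF-kB genes tested carries the 7-mer described next in its 3' UTR, but only 6.09% of the 10170 genes scored carry it. Its absence from so few genes therefore cannot decide on a hairpin seed, and an indirect effect through other genes was not tested.

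Of 16126 7-mers scored in 3' UTRs, GATTATC had the lowest score (-8.04), followed by GGATTAT (-4.72), which overlaps it by 6 bases and also lies in the NPL mRNA, while the lowest from outside that mRNA was -4.02. The 619 carriers of GATTATC were lower by 0.0551 on the log2 scale on average, 17.3% of them changed and lower against 13.4% of other genes, and the shift was -0.0018 (SE 0.0036) for genes with only the last 6 bases; a 7-mer given a simulated shift of 0.05 scored lowest of all in 19 of 20 simulations. Off-target repression through a hairpin seed could give such a shift and GATTATC lies in the NPL mRNA, but so do 16.8% of all 7-mers scored, so the lowest of all falls there by chance that often, and with no hairpin sequence this explanation cannot be told apart from another reason for the shift. Of the 8 extensions of GATTATC by 1 base, the 2 that lie in the NPL mRNA had shifts of -0.0422 (SE 0.009, GATTATCT) and -0.0474 (SE 0.0133, GGATTATC). The other 6, which do not, had -0.0415 to -0.0788, the lowest for GATTATCA (SE 0.014). The seed tested here is the 7-mer alone, whatever base lies beside it, so these shifts cannot decide for or against a hairpin seed. The larger decreases stay open too: 2 of the 23 genes other than NPL that were at least 2-fold lower and have an annotated 3' UTR carry GATTATC, so this seed would leave 21 without a site, while other seeds of an unknown hairpin cannot be excluded.

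The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 3131 changed genes, 177 at 2-fold and 12 lists, and 1 of 10 splits, the real one, reached each of these values. The highest of the other splits were 0, 0 and 7. Each other split mixes both groups on each side, which widens the spread within a side and lowers its gene counts. Those counts therefore do not show what chance alone would give. For chromosomes, all 10 splits gave 0.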
